A study of Mus musculus with 45 samples.

How the data were processed

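RNA from sorted mouse CD4+CD8+ double-positive thymocytes was measured on 45 whole-transcript Affymetrix arrays, 1 array per sample. The labels gave each sample a stage, pre-selection (TCRβ-negative, CD69-negative) or post-selection (TCRβ-positive, CD69-positive), and 1 of 4 genotypes of the cells in the chimeras. The genotypes were wild type, deletion of Pten by Cd4-Cre, and deletion of Pten together with Raptor or with Rictor. The groups held 7 arrays (pre_WT), 4 (pre_Pten), 8 (pre_PtenRaptor), 5 (pre_PtenRictor), 4 (post_WT), 5 (post_Pten), 7 (post_PtenRaptor) and 5 (post_PtenRictor). Numbers in the titles fell into 3 consecutive series, here called title runs 1, 2 and 3, with 13, 16 and 16 arrays. Run 1 held no PtenRaptor array, run 2 no PtenRictor array and run 3 no post_WT array. Whether a pre and a post array came from 1 animal was not stated, so samples were treated as independent and every p-value measures spread between arrays.

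The deposited values were log2 probe set signals. The authors named RMA (version not given) and Affymetrix Expression Console 1.1 in their processing notes, without the role of each tool. The values lay between 3.91 and 14.6, with array medians from 8.22 to 8.39, and no further normalization was applied. The correlation between pairs of arrays ran from 0.945 to 0.995, and no pair held identical values. For arrays the number of samples limits the precision. Of 28846 probe sets, 6640 were control probe sets and 2634 transcript probe sets had no listed gene symbol. The remaining 19572 had 1 symbol each, and all of their identifiers matched the RefSeq table of assembly GRCm38.p6, used for names only, with 0 symbols changed. The probe set with the highest mean stood for each of 55 genes with several, which left 19505 genes, without a filter on dim signals. Pten itself was not analysed here, and no genome positions were used.

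Differences were estimated with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings. Each gene's p-value was adjusted within a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The fit chosen before the data were examined, here the planned fit, took all 45 arrays with 1 coefficient per group and an additive term for title run. Its 16 comparisons, the gene lists, the rule for named genes and the retained share were fixed at that time too. A second fit, chosen after the data had been seen, took the 29 arrays of runs 1 and 2, with a run term for each stage. It was added because stage markers of 8 arrays in run 3 went against their stage labels, and it is here called the fit of runs 1 and 2. Differences are given as log2 values with the standard error of the fit. No array was moved to another group in any fit.

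Named genes were Rptor and Rictor, the 8 called genes with the largest rise and the 8 with the largest fall in each comparison, and up to 4 members with the smallest adjusted p of each list described. The rise or fall had to go the same way in every run that held both groups. Predicted genes, receptor and immunoglobulin segments and small RNAs were left out. Any other gene named was chosen after its values were seen, and the text says so. A summary added after the data had been seen left out the stage differences and PtenRaptor against PtenRictor. Of 120 named rises and falls in the planned fit that a run could show, 116 had the same direction against the control mean of its run in every array of the group, as did 135 of 135 in the fit of runs 1 and 2.

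The 22 gene lists were written from general knowledge and held 463 entries, of which 410 were measured. They covered the PI3K-AKT-mTOR pathway, glycolysis, cholesterol synthesis, fatty acid synthesis, ribosome biogenesis with MYC targets, the amino acid and integrated stress response, oxidative phosphorylation, the cell cycle, FOXO1 targets, and TCR signal with positive selection. They also covered pre-selection double-positive cells, the innate-like T cell program, the interferon response, mature single-positive, double-negative, γδ T, B, myeloid with dendritic, NK with cytotoxic, erythroid and thymic epithelial cells, and immediate early genes with dissociation stress. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. The alternatives were camera with an estimated correlation and fry. Counts of members called over all genes stand beside counts adjusted over the list alone.

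The retained share asked how much of the Pten effect was left in cells that also lacked Raptor or Rictor. Values were adjusted for run with limma's removeBatchEffect. In each of 100 random splits, genes were called in 1 part of the Pten and wild type arrays at p under 0.01 and a log2 difference of at least 0.5. The signed mean difference to wild type was then taken in the other part, for the double deletion and for Pten. The median ratio of both over the splits is given in percent, with its SD. The overlap of calls counted genes called in Pten against wild type and also called, in the opposite direction, in the double deletion against Pten. It was set beside the number from independent lists and from 20 simulations of unchanged groups that share the Pten arrays, with the covariance of both, and was counted again with the Pten arrays divided between the comparisons. The stage position of an array was its signed mean over 360 genes called between wild type stages in runs 1 and 2 with a difference of at least 1 log2, scaled to 0 at the wild type pre mean and 1 at the post mean.

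Alternatives were no run term, title run as a random block, each run alone, quantile normalization again, median centring, a filter that kept the 10820 genes above 8.41 log2 in at least 4 arrays, and only the groups compared. Array weights, eBayes with trend and robust settings, the mean of a gene's probe sets, and leaving out each array in turn were also tried. Those added after the data had been seen were a run term for each stage with all arrays, the Kdm5d level as a covariate, title pairs as a replicate block, the fit of runs 1 and 2 with its own alternatives, and gene lists without pre_WT replicate 4 or pre_Pten replicate 1. Pten against wild type was tested on simulated data at each stage and in both fits, with 19505 genes each. There 58.2% to 68.7% of genes shifted by 0.5 log2 were called, 97.0% to 98.5% of those shifted by 1 log2 and 100% of those shifted by 2 log2, and 10 to 13 unchanged genes were called. A share of 0.5 set for PtenRaptor before selection was estimated at 0.496.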

Results

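The 45 arrays profiled CD4+CD8+ double-positive thymocytes, the thymic T cell precursors that undergo positive selection, sorted from mouse chimeras. Cells were labelled pre-selection or post-selection and were wild type (WT), lacked Pten, or lacked Pten together with Raptor (PtenRaptor) or Rictor (PtenRictor). Pten is the lipid phosphatase that opposes PI3K, and Raptor and Rictor are the defining subunits of the mTOR complexes mTORC1 and mTORC2. The series title asks whether removing either subunit rescues the effect of Pten loss, in connection with an innate-like T cell fate. The planned fit used 7 pre_WT, 4 pre_Pten, 8 pre_PtenRaptor, 5 pre_PtenRictor, 4 post_WT, 5 post_Pten, 7 post_PtenRaptor and 5 post_PtenRictor arrays. The fit of runs 1 and 2 used 5, 3, 4, 3, 4, 3, 4 and 3 arrays in the same order. Errors are the standard error of the limma fit unless another is named, differences are in log2 units, and adjusted p-values of genes come from limma.

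Wild type cells after selection carried far more transcript of genes of TCR signalling and far less of genes of the cell cycle than those before selection, in the fit of runs 1 and 2. Cd226, an adhesion co-receptor, differed by 3.45 ± 0.14, adjusted p = 5.6e-16, and Nr4a3, an orphan nuclear receptor induced by TCR signals, by 3.40 ± 0.15, adjusted p = 2.49e-15. Of the 24 measured genes of TCR signal and positive selection 20 rose, or 22 adjusted over the list alone (camera adjusted p = 8.19e-32, and adjusted p = 0.000405 with an estimated correlation), among them Itm2a (2.50 ± 0.10) and the early response factor Egr2 (2.12 ± 0.09). Of 27 cell cycle genes 26 fell, or 27 adjusted over the list alone (camera adjusted p = 6.75e-37, and adjusted p = 0.00471 with an estimated correlation), with Mki67, the proliferation marker, at -1.39 ± 0.10. Of 13 genes of pre-selection cells 11 fell, as many as when adjusted over the list alone (camera adjusted p = 1.58e-16, and adjusted p = 0.00471 with an estimated correlation), with the recombinase subunit Rag2 at -1.74 ± 0.13 and the terminal transferase Dntt at -1.24 ± 0.10. The cytokine receptor Il7r (2.91 ± 0.21) and the GTPase Gimap3 (2.87 ± 0.19) rose too, and Insl5 fell by 2.48 ± 0.15.

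Between wild type stages 2857 genes were called in the fit of runs 1 and 2, 1385 higher and 1472 lower after selection. The planned fit, which also holds the arrays labelled pre_WT in run 3, called 294 genes, 95 higher and 199 lower, and 292 of them were called in both fits with the same direction. There the same lists gave 2 of 24 TCR genes risen, 0 of 27 cell cycle genes fallen and 2 of 13 pre-selection genes fallen, or 18, 2 and 8 adjusted over each list alone (camera adjusted p = 3.23e-09, 9.28e-11 and 2.17e-07), and each of these calls was lost with an estimated correlation (adjusted p = 0.533). The planned count ran from 39 to 938 without 1 pre_WT array, and from 1 to 565 without 1 post_WT array.

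The stage position scored each array over 360 genes, from 0 at the pre_WT mean to 1 at the post_WT mean of runs 1 and 2. In those runs arrays labelled pre lay between -0.07 and 0.09, and arrays labelled post between 0.51 and 0.73 in run 1 and between 1.08 and 1.28 in run 2. In run 3, 5 arrays labelled pre lay at the post level, at 1.24 (pre_WT replicate 6), 0.79 (pre_WT replicate 7), 1.04 (pre_Pten replicate 4), 1.11 (pre_PtenRaptor replicate 5) and 1.03 (pre_PtenRaptor replicate 6). Another 3 arrays labelled post lay at the pre level, at 0.047 (post_Pten replicate 4), 0.040 (post_Pten replicate 5) and 0.043 (post_PtenRaptor replicate 5). Cd69, a surface marker of the post-selection sort, read 9.08 to 10.9 in arrays labelled pre of runs 1 and 2 and 12.1 to 12.7 in arrays labelled post. It read 12.4 to 12.6 in the 5 arrays and 10.5 to 11.02 in the 3 arrays. Every array kept its label in both fits, so planned comparisons of genotypes hold arrays on either side of the stage position.

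**Figure D1:**
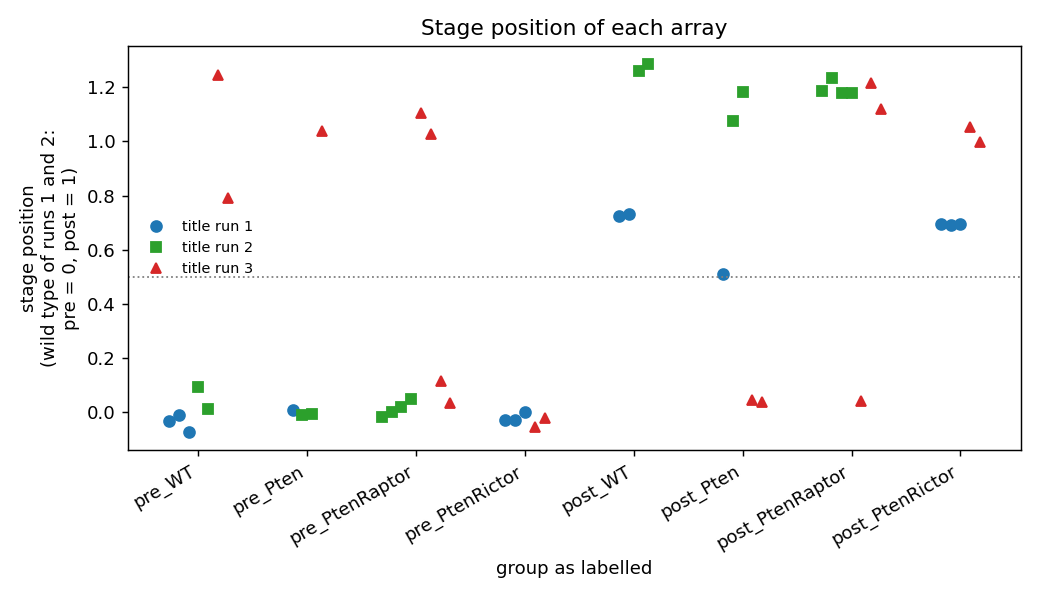
Stage position of each array (vertical axis, 0 at the wild type pre mean and 1 at the wild type post mean of runs 1 and 2) by group and title run, with 1 point per array. In runs 1 and 2 arrays labelled pre lie between -0.07 and 0.09, while 5 arrays of run 3 labelled pre lie from 0.79 to 1.24 and 3 labelled post from 0.040 to 0.047.

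Before selection, the comparison of Pten with wild type asked what loss of Pten changed in cells without surface TCRβ. Pik3r3, a regulatory subunit of PI3K, rose by 1.32 ± 0.11, adjusted p = 1.24e-10 in the planned fit, the largest rise named there, and by 1.33 ± 0.11, adjusted p = 3.1e-08 in the fit of runs 1 and 2. Cmah, the hydroxylase of sialic acid synthesis, was at -1.502 ± 0.24 (adjusted p = 0.000589) and -1.65 ± 0.19 (adjusted p = 1.09e-05). The T-box factor Tbx6 stood at -1.01 ± 0.12, adjusted p = 5.04e-06 in the planned fit. Each held in 4 of 4 arrays. Id2, an inhibitor of E proteins, stood at 1.01 ± 0.13, adjusted p = 2.93e-05 in the fit of runs 1 and 2 and at 0.64 ± 0.32, adjusted p = 0.611 in the planned fit. In run 3 alone, with 1 pre_Pten and 2 pre_WT arrays, Pik3r3 was at 1.20, Tbx6 at -0.72 and Cmah at -1.50 (adjusted p = 0.581, 0.581 and 0.9998).

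The planned fit called 113 genes between Pten and wild type before selection, 18 higher and 95 lower. The fit of runs 1 and 2 called 484, 195 higher and 289 lower, and 96 were called in both with the same direction. Without pre_Pten replicate 1 these counts were 31 and 38, and the count of runs 1 and 2 was 297 without pre_WT replicate 2 and 1048 without pre_WT replicate 4.

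Targets of FOXO1, a factor that PI3K signalling keeps out of the nucleus, were lower as a group in Pten cells before selection. In the planned fit 2 of 20 fell and 7 fell adjusted over the list alone (camera adjusted p = 5.39e-07, and adjusted p = 0.00635 with an estimated correlation). The ubiquitin ligase Fbxo32 was at -0.46 ± 0.09, adjusted p = 0.00548, and had adjusted p = 0.0531 without a run term and 0.0840, 0.564 and 0.9998 in run 1, 2 and 3 alone. In the fit of runs 1 and 2, 5 of 20 fell and 1 rose, with 12 fallen and 1 risen adjusted over the list alone (camera adjusted p = 1.11e-06), a call lost with an estimated correlation (adjusted p = 0.0918) and without pre_Pten replicate 1 (adjusted p = 0.301). Camera in the planned fit also placed cholesterol synthesis, glycolysis, ribosome biogenesis, the amino acid response, oxidative phosphorylation and the cell cycle higher, with 0 members called in each, and adjusted p ran from 0.122 to 0.704 with an estimated correlation. Without pre_Pten replicate 1 the ribosome list turned lower (adjusted p = 0.000448) and the glycolysis, amino acid response and cell cycle lists lost their call and turned sign (0.987, 0.690 and 0.854), while cholesterol synthesis (0.0732) and oxidative phosphorylation (0.854) lost theirs. It placed TCR signal (0 of 24 members fallen), the interferon response (0 of 26), mature single-positive markers (1 of 16), and B, NK and erythroid cell markers (0 of 11, 0 of 9 and 0 of 7) lower, each lost with an estimated correlation (adjusted p from 0.16 to 0.684). The TCR list also lost its call without pre_Pten replicate 1 (0.854). In pre_WT replicate 4 the mean signal of B, erythroid and myeloid markers was 9.51, 9.64 and 8.64, against at most 8.12, 8.56 and 7.87 in the other pre_WT arrays. Without that array the erythroid list turned sign (adjusted p = 0.948) and the glycolysis and NK lists lost their call (0.104 each).

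After selection, the same comparison asked what Pten loss changed in cells that had received a TCR signal. Pik3r3 rose again, by 0.97 ± 0.12, adjusted p = 9.35e-06 in the planned fit and 1.13 ± 0.11, adjusted p = 1.07e-06 in the fit of runs 1 and 2. The histamine receptor Hrh2 fell by 1.37 ± 0.20 (adjusted p = 0.000216) and 1.20 ± 0.13 (adjusted p = 3.52e-06). The immunoglobulin superfamily gene Igsf23 (1.40 ± 0.21, adjusted p = 0.000314) and the leucine zipper factor Tsc22d1 (1.07 ± 0.18, adjusted p = 0.00275) rose in the planned fit. Their calls in the fit of runs 1 and 2 (1.31 ± 0.20 and 1.12 ± 0.17) ended without post_Pten replicate 1 (adjusted p = 0.163 and 0.104). The membrane protease Mmp14 (1.45 ± 0.11, adjusted p = 1.43e-08) and the adhesion receptor Cd44, a marker of activated and memory T cells (1.37 ± 0.21, adjusted p = 0.000967), were higher in the fit of runs 1 and 2, while Cmah was at -1.46 ± 0.20, adjusted p = 0.000186. In the planned fit Mmp14 was at 1.08 ± 0.26, adjusted p = 0.0504 and Cd44 at 0.62 ± 0.44, adjusted p = 0.539.

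The planned fit called 55 genes between Pten and wild type after selection, 23 higher and 32 lower. That of runs 1 and 2 called 101, 47 higher and 54 lower, with 31 called in both and the same direction. Without 1 array the planned count ran from 10 (post_Pten replicate 1) to 105 (post_Pten replicate 3) and that of runs 1 and 2 from 28 (post_Pten replicate 1) to 76.

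Genes of the cell cycle and of pre-selection cells were higher as lists in post_Pten arrays in the planned fit, and those of TCR signal, the interferon response and mature single-positive cells were lower, but no member of these lists was called over all genes. Adjusted over the list alone, 0 of 27 cell cycle genes and 0 of 24 TCR genes passed, as did 5 of 26 interferon genes (lower) and 4 of 16 mature single-positive markers (lower). Camera's adjusted p was 7.9e-11 for the cell cycle and 6.53e-06 for TCR signal, and with an estimated correlation the adjusted p of these 5 lists ran from 0.268 to 0.481. The post_Pten group holds the 2 arrays of run 3 at the pre level of the stage position, where the same genes differ. Cholesterol synthesis was higher (1 of 19 risen) and ribosome biogenesis lower (0 of 26 fallen), at adjusted p = 0.268 and 0.823 with an estimated correlation. The innate-like T cell list was not called in Pten against wild type at either stage, in either fit.

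Of the genes called in Pten against wild type, 17 were called at both stages in the planned fit and 39 in the fit of runs 1 and 2, all in the same direction, where independent lists would share 0.319 and 2.51. The stage difference of the Pten effect itself had 0 called genes in the planned fit (limma, 1400 at an unadjusted p under 0.05). That in the fit of runs 1 and 2 had 4, named after their values were seen: Insl5 (1.44), the cholesterol exporter Abca1 (1.35), Mmp14 (1.04) and Tube1 (0.96), each higher after selection. All 4 calls ended without pre_Pten replicate 1, at adjusted p = 0.429, 0.678, 0.321 and 0.678. Each also ended when any of 3 or more other arrays was left out, at adjusted p from 0.0517 to 0.160. The count ran from 0 without post_WT replicate 4 or post_Pten replicate 2 to 33 without pre_WT replicate 4.

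Pik3r3 was lower in cells that lacked Raptor as well as Pten than in Pten cells before selection, by 0.72 ± 0.11 in the planned fit (adjusted p = 0.000517) and 0.81 ± 0.11 in the fit of runs 1 and 2 (adjusted p = 0.00139), in 8 of 8 arrays. The vasopressin receptor Avpr2 was higher, by 0.62 ± 0.09, adjusted p = 0.000517 in the planned fit, with adjusted p = 0.106 in the fit of runs 1 and 2. Id2 (-0.91 ± 0.13, adjusted p = 0.00207) was lower in the fit of runs 1 and 2, and the Rho effector Rtkn (0.86 ± 0.11, adjusted p = 0.00036) higher. With only the groups compared in the model, Pik3r3 and Avpr2 lost their planned call (adjusted p = 0.150 and 0.227) and Id2 its call (0.0622), and with 1 run term for both stages Id2 had 0.0573. Fits of a single run ended the planned calls, for Avpr2 at 0.43 (adjusted p = 0.229) in run 2 and 0.84 (0.712) in run 3, and for Pik3r3 at -0.64 (0.9994) in run 3.

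The planned fit called 10 genes between PtenRaptor and Pten before selection, 9 higher and 1 lower. That of runs 1 and 2 called 9, 3 higher and 6 lower, with 1 in both. With 1 array left out the planned count ran from 2 (pre_Pten replicate 4) to 26 (pre_Pten replicate 3). Camera in the planned fit placed cholesterol synthesis, ribosome biogenesis, the amino acid response, oxidative phosphorylation and the cell cycle lower and FOXO1 targets and pre-selection genes higher, with 0 members called in each, and adjusted p ran from 0.125 to 0.75 with an estimated correlation. Without pre_Pten replicate 1 the ribosome (adjusted p = 0.148) and cell cycle (0.890) lists turned sign and all but cholesterol synthesis lost their call.

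After selection, cells without Pten and Raptor had lower Pik3r3 than Pten cells, at -0.79 ± 0.10 in the planned fit (adjusted p = 3.3e-05) and -1.09 ± 0.12 in the fit of runs 1 and 2 (adjusted p = 4.7e-06). The cell cycle factor E2f2 (-1.08 ± 0.12, adjusted p = 6.39e-06), Mns1 (-1.11 ± 0.10, adjusted p = 7.29e-07) and the galectin Lgals1 (-0.999 ± 0.12, adjusted p = 4.07e-05) fell in the fit of runs 1 and 2. Cholesterol synthesis genes were lower as a group in both fits, with 0 of 19 members fallen and 4 fallen adjusted over the list alone in the planned fit (camera adjusted p = 8.27e-09, and adjusted p = 0.0339 with an estimated correlation). The values in the fit of runs 1 and 2 were 0 of 19, 2, 1.05e-07 and 0.0258, and the sterol dehydrogenase Nsdhl was at -0.39 ± 0.10, adjusted p = 0.276 in the planned fit. The cell cycle list was lower, with 0 of 27 called over all genes and 20 fallen adjusted over the list alone in the fit of runs 1 and 2 (camera adjusted p = 2.72e-22, and adjusted p = 0.0275 with an estimated correlation). In the planned fit 13 cell cycle genes fell adjusted over the list alone, and the adjusted p was 0.412 with an estimated correlation. With only the groups compared in the model, the planned call of Pik3r3 had adjusted p = 0.242, and in run 3 alone it was at -0.38 (0.656).

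In the same comparison of runs 1 and 2, interferon response genes and immediate early genes were lower as groups. Of 26 interferon genes 3 fell and 10 adjusted over the list alone (camera adjusted p = 2.27e-15, and adjusted p = 0.0156 with an estimated correlation). The antiviral effector Ifit1 fell by 0.75 (adjusted p = 0.0217), a call that ended without post_Pten replicate 1 (0.0725) or 3 (0.377), or without post_PtenRaptor replicate 1 (0.0726). It also ended without a run term (0.844) and in other settings of the model (from 0.0992 to 0.813). Of 17 immediate early and dissociation stress genes 4 fell and 9 adjusted over the list alone (camera adjusted p = 8.25e-13, and adjusted p = 0.00961 with an estimated correlation). The heat shock gene Hspa1b fell by 0.87 (adjusted p = 0.0147), a call that ended without post_Pten replicate 2 (0.0642) or 3 (0.371), and in other settings of the model (from 0.0781 to 0.192). Neither list was called in the planned fit. Called genes were 3 in the planned fit (1 higher, 2 lower) and 46 in runs 1 and 2 (7 higher, 39 lower). Both fits shared 1. The planned count was 53 without post_PtenRaptor replicate 5, and that of runs 1 and 2 ran from 11 (post_Pten replicate 3) to 55 without 1 array. Camera also called oxidative phosphorylation, TCR signal and pre-selection genes in the planned fit, at adjusted p from 0.423 to 0.845 with an estimated correlation.

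Against wild type, cells without Pten and Raptor still differed before selection. The coiled-coil gene Ccdc152 fell by 1.62 ± 0.20 (adjusted p = 1.84e-06), the interferon-induced Epsti1 by 1.23 ± 0.15 (adjusted p = 2.18e-06) and Slc28a2b, of the nucleoside transporters, by 1.03 ± 0.14 (adjusted p = 2.15e-05) in the planned fit. The values in the fit of runs 1 and 2 were -1.84 ± 0.24, -1.82 ± 0.13 and -1.54 ± 0.14. Pik3r3 was higher than in wild type, by 0.60 ± 0.09, adjusted p = 0.000248 in the planned fit and 0.52 ± 0.11, adjusted p = 0.015 in the fit of runs 1 and 2. The latter call ended without pre_WT replicate 5 (0.101), without pre_PtenRaptor replicate 2 (0.0518) and in other settings of the model (0.0538 and 0.0817). Of 16 markers of mature single-positive cells 1 fell and 5 adjusted over the list alone in the planned fit (camera adjusted p = 1.2e-09, and adjusted p = 0.0251 with an estimated correlation). In the fit of runs 1 and 2 the list had adjusted p = 0.0862 with an estimated correlation and lost its call without pre_WT replicate 4 (0.0796). Camera also placed FOXO1 targets, TCR signal, the interferon response and B, NK and erythroid markers lower in the planned fit, at adjusted p from 0.0994 to 0.708 with an estimated correlation. B, erythroid and myeloid markers stood high in pre_WT replicate 4. Called genes were 66 in the planned fit (22 higher, 44 lower) and 304 in runs 1 and 2 (110 higher, 194 lower). Both fits shared 50 in the same direction. Without 1 array the counts ran from 42 to 79 and from 167 to 503 (pre_WT replicate 4). In run 3 alone these calls ended (adjusted p from 0.707 to 0.732), with Ccdc152 at -1.40, Epsti1 at -0.57, Slc28a2b at -0.75 and Pik3r3 at 0.56.

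Against wild type after selection, Hrh2 was lower in cells without Pten and Raptor, at -1.30 ± 0.19 in the planned fit (adjusted p = 0.000284) and -1.47 ± 0.13 in the fit of runs 1 and 2 (adjusted p = 1.52e-07). Cd44 rose in the fit of runs 1 and 2, by 1.61 ± 0.22, adjusted p = 0.000189. There Mmp14 rose by 0.99 ± 0.12, adjusted p = 2.5e-05 and the β-tubulin Tubb2b fell by 1.48 ± 0.13 (adjusted p = 8.69e-08). In the planned fit Cd44 was at 1.15 ± 0.42, adjusted p = 0.224, Mmp14 at 0.73 ± 0.25, adjusted p = 0.183 and Tubb2b at -1.17 ± 0.29, adjusted p = 0.059. Of 26 interferon genes 6 fell and 17 adjusted over the list alone in the fit of runs 1 and 2 (camera adjusted p = 1.45e-16, and adjusted p = 0.0205 with an estimated correlation), with the antiviral synthetase Oas2 at -0.82 ± 0.15, adjusted p = 0.00393. Without a run term Oas2 had adjusted p = 0.0620, with run as a random block 0.0595 and with only the groups compared 0.0881. In the planned fit 1 of 26 fell and 5 adjusted over the list alone (camera adjusted p = 1.25e-05), and the adjusted p was 0.641 with an estimated correlation, as for mature single-positive and immediate early genes (0.641 each) and myeloid markers (0.795). Called genes were 64 in the planned fit (38 higher, 26 lower) and 129 in runs 1 and 2 (34 higher, 95 lower). Both fits shared 29 in the same direction. Without 1 array the planned count ran from 18 (post_WT replicate 1) to 226 (post_WT replicate 3), and that of runs 1 and 2 from 51 (post_WT replicate 4) to 143.

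Pik3r3 was lower in cells that lacked Rictor as well as Pten than in Pten cells before selection, by 0.88 ± 0.12 in the planned fit (adjusted p = 0.000116) and 0.81 ± 0.14 in the fit of runs 1 and 2 (adjusted p = 0.00365). Avpr2 was higher, by 0.69 ± 0.10, adjusted p = 0.000526 in the planned fit. The second call of Pik3r3 ended without pre_Pten replicate 1 (0.292) and with array weights (0.0623). FOXO1 targets were higher as a group than in Pten cells, with 0 of 20 members called over all genes and 5 risen adjusted over the list alone in the planned fit (camera adjusted p = 9.16e-05, and adjusted p = 0.0408 with an estimated correlation). Fbxo32 was at 0.45 ± 0.10, adjusted p = 0.0604. The call of this list ended without pre_Pten replicate 1 (adjusted p = 0.225). Camera also placed glycolysis, cholesterol synthesis, ribosome biogenesis and the amino acid response lower and the cell cycle, pre-selection genes and B cell markers higher in the planned fit, with 0 members called in each and adjusted p from 0.218 to 0.794 with an estimated correlation. Without pre_Pten replicate 1 ribosome biogenesis (0.0580) and the amino acid response (0.930) turned sign, and only the cell cycle and B cell markers kept their call. In the fit of runs 1 and 2 differences named by the rule included Sdc4, a heparan sulfate proteoglycan (-1.98 ± 0.34, adjusted p = 0.00365), and Cmah (1.61 ± 0.24, adjusted p = 0.0025). Both calls ended without pre_Pten replicate 1 (0.969 and 0.908), the only pre_Pten array of run 1, where all PtenRictor arrays of this fit lie. They also ended with array weights (0.249 and 0.203), and that of Cmah without a run term (0.191) and with the random block (0.140). Called genes were 21 in the planned fit (14 higher, 7 lower) and 237 in runs 1 and 2 (105 higher, 132 lower). Both fits shared 15 in the same direction. Without 1 array the counts ran from 2 to 36 and from 0 to 522, lowest without pre_Pten replicate 1 and highest without replicate 3. In run 3 alone Pik3r3 was at -0.86 and Avpr2 at 0.77 (adjusted p = 0.284 each).

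After selection, Hrh2 was higher in cells without Pten and Rictor than in Pten cells, by 1.11 ± 0.19, adjusted p = 0.00532 in the planned fit and 1.28 ± 0.16, adjusted p = 0.000218 in the fit of runs 1 and 2. Gimap3 was higher by 2.01 ± 0.27, adjusted p = 0.000428 in the latter. Pik3r3 was lower, by 0.78 ± 0.11 in the planned fit (adjusted p = 0.000471) and by 0.85 ± 0.14 in the fit of runs 1 and 2 (adjusted p = 0.00308), the last call ending without post_Pten replicate 1 (0.165). The call of Gimap3 in runs 1 and 2 ended without a run term (0.715) or with 1 run term for both stages (0.248), and that of Hrh2 without a run term (0.147). In run 3 alone Hrh2 was at 1.30 and Pik3r3 at -0.64 (adjusted p = 0.216 and 0.330). Camera in the planned fit placed PI3K pathway components, TCR signal and mature single-positive markers higher and the cell cycle and pre-selection genes lower, with 0 members called in each and adjusted p from 0.657 to 0.781 with an estimated correlation. Called genes were 25 in the planned fit (19 higher, 6 lower) and 29 in runs 1 and 2 (21 higher, 8 lower). Both fits shared 7 in the same direction. Without 1 array the planned count ran from 6 to 24 and that of runs 1 and 2 from 6 (post_Pten replicate 1) to 31.

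Against wild type, limma called 0 genes in cells without Pten and Rictor at either stage and in either fit. At an unadjusted p under 0.05 there were 825 genes before and 2620 after selection in the planned fit, and 550 and 2299 in the fit of runs 1 and 2. In the fit of runs 1 and 2 Pik3r3 was at 0.52 ± 0.11, adjusted p = 0.762 before and 0.28 ± 0.12, adjusted p = 0.391 after selection. Cmah was at -0.04 ± 0.20, adjusted p = 1 and 0.04 ± 0.22, adjusted p = 0.957, and Cd44 after selection at 0.28 ± 0.23, adjusted p = 0.634. With array weights the count was 117 after selection in the planned fit, and 3 before and 914 after selection in the fit of runs 1 and 2. Without 1 array it reached 1 before and 13 after selection (post_WT replicate 3) in the planned fit, and 1 at each stage in runs 1 and 2. Before selection, camera in the planned fit called 11 lists, among them the innate-like T cell list (lower, 0 of 32 members called), the cell cycle (higher), TCR signal (lower), and B, myeloid and erythroid markers (lower), which stood high in pre_WT replicate 4. All 11 were lost with an estimated correlation (adjusted p from 0.306 to 0.611).

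The genes called in Pten against wild type were followed in the double deletions, a summary added after the data had been seen. Before selection 111 of 113 genes of the planned fit lay on the same side of wild type in PtenRaptor (34 called, limma). In PtenRictor it was 102. After selection it was 55 of 55 (20 called) and 51. In the fit of runs 1 and 2 it was 473 of 484 (158 called) and 249 before selection. After it the numbers were 94 of 101 (36 called) and 70. PtenRictor had 0 called genes in all, so calls do not compare genotypes (Pik3r3 before selection was at 0.52 in both in runs 1 and 2). These comparisons share their wild type arrays, which alone makes such directions coincide.

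The retained share lessens this by selecting genes in 1 part of the arrays and measuring them in the other. Both differences still share wild type arrays there. In the planned setting PtenRaptor cells retained 71.1% ± 18.6 (SD over splits, n = 8 arrays) of the Pten effect before selection and 41.03% ± 13.7 (n = 7) after it. PtenRictor cells retained 20.2% ± 48.5 (n = 5) and -5.70% ± 26.8 (n = 5). These shares hold the 8 arrays of run 3 out of place, none of PtenRictor, and so mix stages. In runs 1 and 2 alone the shares were 112% ± 21.1 (n = 4) and 70.1% ± 18.1 (n = 4) in PtenRaptor and -4.44% ± 26.5 (n = 3) and 4.73% ± 45.1 (n = 3) in PtenRictor. Both double deletions share no run there, and n counts their arrays. With 3 Pten arrays a stage, 1 part of each split held only 1. The difference was not tested, and the splits are not independent, so their SD is no test.

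In the planned fit 4 genes called in Pten before and 1 after selection were called in the opposite direction in PtenRaptor against Pten. Independent lists would share 0.0448 and 0.00400. For PtenRictor the counts were 20 and 11, against 0.0746 and 0.0382 from such lists. The overlaps in runs 1 and 2 were 2 and 13 for PtenRaptor and 172 and 24 for PtenRictor, and PtenRaptor also had 4 and 1 genes called in the same direction. Without pre_Pten replicate 1, PtenRictor against Pten had 2 and 0 called genes before selection in the planned fit and that of runs 1 and 2, which leaves overlaps of at most 2 and 0.

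Both comparisons share their Pten arrays, which alone makes their differences run opposite. The overlap was 0 in 20 simulations of unchanged groups, where calls are rare by design, so this 0 decides nothing. The covariance of the planned differences was -0.0125 in PtenRaptor and -0.0152 in PtenRictor before selection, against -0.0105 and -0.0115 simulated from sharing alone. After selection it was -0.0225 and -0.0255, against -0.00834 and -0.00899. With the Pten arrays divided, a check added after the data had been seen, the overlap averaged 1.5 and 2.67 over 6 divisions before selection. It averaged 0.9 and 1.35 over 20 after it. The mean covariance was then 0.00501 and 0.00392 before selection and -0.0112 and -0.0131 after it. Part of the overlap may therefore come from the shared arrays, and each division holds fewer arrays.

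Compared directly, cells without Pten and Raptor had lower selenoprotein P (Selenop) than cells without Pten and Rictor, at -0.70 ± 0.10, adjusted p = 0.000342 before and -0.66 ± 0.10, adjusted p = 0.00106 after selection in the planned fit. Ccdc152, which lies beside Selenop, was at -1.49 ± 0.23, adjusted p = 0.000639 before selection, and Hrh2 at -1.04 ± 0.19, adjusted p = 0.00851 and Ccdc125 at -0.64 ± 0.08, adjusted p = 4.9e-05 after it. Both genotypes shared only run 3, where the calls were lost at -0.70 for Selenop (adjusted p = 0.303) and -1.18 for Ccdc152 (0.316) before selection, and at -0.54, -0.92 and -0.57 for Selenop, Hrh2 and Ccdc125 after it (0.9998 each). With only the groups compared they were lost for Ccdc152 (0.0590) and for Selenop (0.110 before and 0.436 after) and Ccdc125 (0.342). The planned fit called 4 genes before selection, 0 higher and 4 lower, and 12 after it, 2 higher and 10 lower. The fit of runs 1 and 2 called 41 and 20. Without 1 array the planned counts ran from 2 to 8 before and from 7 to 25 (post_PtenRaptor replicate 5) after selection. FOXO1 targets were lower in PtenRaptor at both stages by camera (0 of 20 called), at adjusted p = 0.928 before and 0.0797 after selection with an estimated correlation. The stage differences of PtenRaptor and of PtenRictor against Pten had 0 called genes each (limma, 1384 and 1720 at an unadjusted p under 0.05). Without 1 array the first reached 5 and the second 1.

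**Figure D2:**
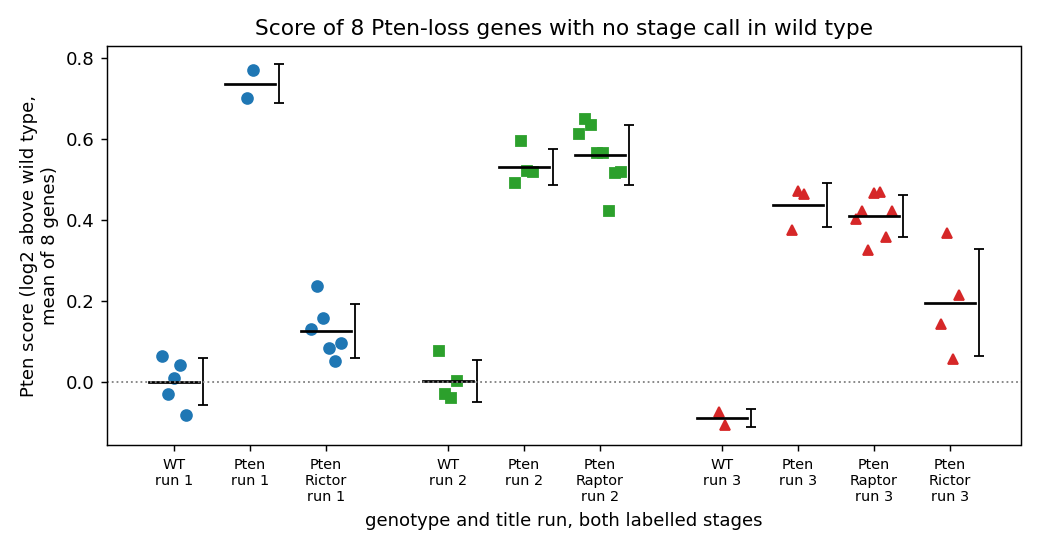
Mean signed level of 8 genes called in Pten against wild type at both stages (log2, vertical axis, 0 at the wild type mean of runs 1 and 2) by genotype and title run; points are arrays of both labelled stages, black lines means and bars SD. Wild type lies at -0.00, 0.00 and -0.09 in runs 1, 2 and 3, Pten at 0.74, 0.53 and 0.44, PtenRaptor at 0.56 and 0.41 in runs 2 and 3, and PtenRictor at 0.13 and 0.19 in runs 1 and 3.

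The transcripts of the deleted subunits were not called lower over all genes. The planned fit put Rptor in PtenRaptor against Pten at -0.24 ± 0.09 (adjusted p = 0.47) before and -0.10 ± 0.09 (0.796) after selection. That of runs 1 and 2 gave -0.40 ± 0.10 (0.155) and -0.21 ± 0.10 (0.73). There pre_PtenRaptor arrays read 10.59 to 10.70 in Rptor, below pre_Pten (11.01 to 11.07) and pre_WT (10.81 to 10.89). After selection PtenRaptor and Pten overlapped. Rictor in PtenRictor against Pten was at -0.03 ± 0.12 (0.995) and 0.15 ± 0.11 (0.654) in the planned fit. In runs 1 and 2 it was at 0.09 ± 0.16 (0.898) and 0.24 ± 0.17 (0.769). Whether the probes of these genes lie in the deleted part was not given, and Pten was not analysed. The Y-linked gene Kdm5d read above 8 log2 in 11 of 45 arrays, with 2 of 4 pre_Pten, 3 of 5 post_Pten and 1 in each other group.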

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

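All tests of the 8 arrays out of place in run 3 and of the difference between PtenRaptor and PtenRictor, and those of other cell types and of proliferation in pre_Pten replicate 1, were chosen after the results had been seen, while the test of RNA quality and the splits of the samples were written before.

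Of 224 tests for an array far from the rest of its group (Dixon's test, 4 to 8 arrays), 24 found one, or 10.7% where chance gives 5%. Post_PtenRaptor replicate 5 accounted for 9 of them. Its stage position was 0.043, against 1.12 to 1.23 in the other arrays of its group, and its Cd69 signal was 10.8 against 12.4 to 12.7. The mean signal of its cell cycle list was 10.6 against 9.01 to 9.21, of TCR signal 9.68 against 10.9 to 10.97, of pre-selection genes 11.98 against 10.8 to 10.99, of the innate-like T cell list 8.17 against 8.45 to 8.55, of mature single-positive markers 8.07 against 8.51 to 8.69 and of myeloid markers 7.61 against 7.80 to 7.90. Its signed mean of 39 genes of Pten loss was -2.81, against -3.20 to -3.07. The stage position of pre_Pten replicate 4 was 1.04, against -0.0076 to 0.0078, and its γδ T cell markers read 9.03 against 8.42 to 8.52.

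All 8 arrays out of place in run 3 lay inside the range of the other stage in runs 1 and 2. A wrong stage label would give this. For the 3 labelled post their position argues against an incomplete sort. For the 5 labelled pre that stays open, since the post range, from 0.51, would hold mixed cells. Pre_WT replicate 7 (0.79) lay below all others on that side in run 3 (from 0.998). Genotype is argued against, since 2 of the 8 were wild type. By title number the 8 are all arrays from 35 to 41 and from 48 to 51, while all from 42 to 45 and from 53 to 56 lie with their labels. The labels name no sort or animal, so a wrong label is a candidate and no array was moved. Planned comparisons that hold these arrays mix stage and genotype.

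Pre_Pten replicate 1 was the only pre_Pten array of run 1. Its amino acid and integrated stress response list averaged 9.82, against 9.29 to 9.32 in the other pre_Pten arrays, and its cell cycle list exceeded the wild type mean of its run by 0.623. Cells of other types in the sort stay open. Of 7 marker lists of other types 0 were higher in it than in every other pre array of runs 1 and 2, but pre_WT replicate 4 was itself high in several, and without it 2 were higher by little (double-negative markers 7.816 against 7.812, myeloid 7.768 against 7.760) and 5 were not. The sort should remove such cells. RNA quality or array brightness stays open too. Its positive minus negative control probe sets differed by 3.25, inside the 2.71 to 3.29 of all other arrays of those runs but above every other pre array (highest 3.19). An effect of Pten loss on proliferation shared by the group was argued against. The highest excess of a pre_Pten array of run 2 over the wild type mean of run 2 was 0.00233, below 0.623 by more than 2 SD of wild type arrays within a run (SD 0.176), and it was 0.124 over pre_WT replicate 5 alone. This test was the second form tried, after a first form based on ranks within run 2 had been seen. A difference of that animal or its sort may remain, and it was not tested.

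PtenRaptor arrays kept more of the Pten effect than PtenRictor arrays in the retained share, whose planned setting mixes stages. A score over 8 genes called in Pten at both stages in the fit of runs 1 and 2 was used to weigh this. They were Arhgap31, Ccdc125, Dab2ip, Eya2, Igf1r, Pim1, S1pr4 and Tsc22d1, and had an unadjusted p of 0.05 or more between wild type stages. The Pten arrays of run 1 alone stay open as the source. The highest excess of a PtenRictor array of run 1 over its wild type mean was 0.237, below the lowest of a PtenRaptor array of run 2 (0.422), but those Pten arrays took part in choosing the genes. Title run cannot be told apart from genotype in runs 1 and 2, which share no double deletion. In run 3, which holds both, PtenRaptor arrays were higher by 0.215, with a 2-sided exact permutation p of 0.00909 over 330 splits, and this failed the correction over the 6 tests of that run (adjusted p = 0.0545). The verdict moved from the unadjusted to the adjusted p after both had been seen. Averaged over title pairs the difference was 0.216 (4 against 2 units, exact p = 0.0667, the smallest that 15 splits allow). The other 5 tests of that run gave exact p from 0.0278 to 0.433 and 0 of them passed the correction. That loss of Rictor removes more of the Pten effect than loss of Raptor stays open too, since its lower retained share in both of 2 stages is the pattern itself.

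In pre_WT replicate 4 B cell markers averaged 9.51 against 7.88 to 8.12. Myeloid markers read 8.64 against 7.55 to 7.87 and erythroid markers 9.64 against 8.33 to 8.56. The sort should remove such cells, and their presence was not tested further. Pre_PtenRaptor replicate 7 had Rptor at 11.4 against 10.6 to 10.97, oxidative phosphorylation at 10.4 against 11.1 to 11.4 and thymic epithelial markers at 8.24 against 7.93 to 8.05. Its control probe sets differed by 2.32, the lowest of all 45 arrays, so array quality stays open. Thymic epithelial markers of post_PtenRaptor replicate 7 were 8.15 against 7.92 to 8.005, and NK markers of post_PtenRaptor replicate 6 7.86 against 7.37 to 7.58. PI3K pathway components of post_PtenRaptor replicate 3 averaged 9.98 against 10.1 to 10.2, glycolysis of pre_PtenRictor replicate 5 9.86 against 9.68 to 9.71, FOXO1 targets of post_WT replicate 2 10.3 against 10.19 to 10.20 and interferon genes of post_PtenRictor replicate 3 8.51 against 8.65 to 8.69.

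The effect of Pten loss differed between stages in 4 genes in the fit of runs 1 and 2, by 1.35 in Abca1, 1.44 in Insl5, 1.04 in Mmp14 and 0.96 in Tube1, and these calls ended without pre_Pten replicate 1 (adjusted p from 0.321 to 0.678). Camera also called 24 list results on the stage difference, every one lost with an estimated correlation (adjusted p from 0.175 to 0.96). In the planned fit the mean stage difference of Pten against wild type was -0.36 for ribosome biogenesis, 0.45 for the cell cycle, 0.10 for FOXO1 targets, -0.47 for TCR signal, 0.49 for pre-selection genes and 0.25 for B cell markers. For PtenRaptor against Pten it was 0.26 for ribosome biogenesis, -0.64 for the cell cycle, -0.10 for FOXO1 targets, 0.31 for TCR signal and -0.59 for pre-selection genes. That of PtenRictor against Pten was 0.35, -0.59, 0.84 and -0.52 for ribosome biogenesis, the cell cycle, TCR signal and pre-selection genes. In the fit of runs 1 and 2 that of Pten against wild type was -0.15 for glycolysis, -0.47 for ribosome biogenesis, -0.15 for the amino acid response, -0.19 for oxidative phosphorylation and 0.20 for FOXO1 targets. It was 0.32 for pre-selection genes, 0.47 for B cell, 0.26 for myeloid and 0.31 for erythroid markers. The last 2 turned sign without pre_WT replicate 4 (adjusted p = 0.996 and 0.893), and glycolysis and the amino acid response without pre_Pten replicate 1 (0.992 and 0.317), as did ribosome biogenesis for PtenRaptor in the planned fit (0.911).

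Of 2634 transcript probe sets without a listed gene symbol, 20 were called in the planned fit between Pten and wild type before selection, 2 higher and 18 lower, and 12 after it, 5 higher and 7 lower.

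Chance was examined by splitting the samples of each comparison anew into groups of the same sizes. The rule asked that a share under 0.05 of the splits, the real one included, reach the real count. It was not corrected over the comparisons, and the splits moved arrays between title runs, so meeting it does not exclude chance. In the planned fit Pten against wild type met it before (113 genes, 2 of 100 splits, highest other 137) and after selection (55 genes, 4 of 100, highest other 127). PtenRictor against Pten met it before (21 genes, 1 of 100, highest other 2) and after selection (25 genes, 1 of 100, highest other 0). PtenRaptor against Pten did not meet it before selection (10 genes, 5 of 100, highest other 2230). After selection it did (3 genes, 4 of 100, highest other 2314), a margin that does not tell the 2 stages apart. PtenRaptor against wild type met the rule before (66 genes, 2 of 100, highest other 239) and after (64 genes, 2 of 100, highest other 122). The same holds for PtenRaptor against PtenRictor before (4 genes, 4 of 100, highest other 645) and after selection (12 genes, 1 of 100, highest other 0), and for the stages of wild type (294 genes, 2 of 100, highest other 1100). Every split reaches a count of 0, so the splits decide nothing for PtenRictor against wild type (0 genes by limma, with 825 and 2620 at an unadjusted p under 0.05 before and after selection, 100 of 100 splits, highest others 3 and 2). The same goes for the 3 stage differences (0 genes each by limma, 1400, 1384 and 1720 unadjusted, 100 of 100 splits), with highest others of 723 for Pten against wild type, 841 for PtenRaptor against Pten and 0 for PtenRictor against Pten.

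For the fit of runs 1 and 2 chance can be excluded for Pten against wild type before (484 genes, 2 of 56 splits, highest other 2108) and after selection (101 genes, 1 of 34, highest other 52). Chance can be excluded by this rule for PtenRaptor against Pten before (9 genes, 1 of 35, highest other 1) and after (46 genes, 1 of 35, highest other 19), and for PtenRaptor against wild type before (304 genes, 1 of 100, highest other 177) and after (129 genes, 1 of 35, highest other 11). The stages of wild type gave 2857 genes, 1 of 100 splits and a highest other of 1488, which excludes chance. The 10 splits of PtenRictor against Pten are too few for a share under 0.05, with 237 and 29 genes in the real split and a highest other of 0 at each stage. Nothing is decided for PtenRictor against wild type (0 genes by limma, 550 and 2299 unadjusted, 56 of 56 and 35 of 35 splits, highest others 5 and 2). Chance cannot be excluded for the stage difference of Pten against wild type (4 genes, 9 of 100, highest other 1269). Splits that call several times the real count, as in PtenRaptor against Pten of the planned fit, point to a structure of the samples that the labels do not give.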

How the results depend on the processing

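The alternatives named at the outset as added later were chosen after the data had been seen. So were the overlap without a run term or with the Pten arrays divided, and the shares and overlaps of runs 1 and 2. In the planned fit counts of called genes stayed within 1.5 times in 149 alternatives and moved further in 88. In runs 1 and 2 it was 96 and 48. The 149 and 96 include comparisons that stayed at 0 called genes, which inflates them. The cause of a change was not tested, except that fits of a single run and fits without 1 array hold fewer arrays, and the filter tests fewer genes. In estimating array weights limma warned that it had not converged. In run 1 each Pten group holds 1 array, as does pre_Pten in run 3, so counts from those runs alone assume that it varies like the other groups.

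Groups share no replicate number, but in 20 pairs title numbers of pre and post arrays of a genotype differ by a constant within a run. All 20 agree in Kdm5d above or below 8 log2. Residual correlations, only 3 over 0.1, leave a shared animal open, since pairs of arrays out of place lay lowest (-0.705 and -0.657). As a replicate block (consensus correlation -0.0552, and 0.00823 in runs 1 and 2) the pairs gave 123 genes for WT post vs pre. No other count moved by over 1.5 times. In the planned fit 18 calls of named genes ended.

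Without a run term the count was 6 for pre PtenRaptor vs Pten, 11 for pre PtenRictor vs Pten, 20 for pre PtenRaptor vs PtenRictor, 29 for post Pten vs WT, 120 for post PtenRaptor vs WT and 1 for post PtenRictor vs WT. It was 33 for post PtenRaptor vs PtenRictor and 112 for WT post vs pre. With run as a random block the count was 6 for pre PtenRaptor vs Pten, 10 for pre PtenRictor vs Pten, 16 for pre PtenRaptor vs PtenRictor, 5 for post PtenRaptor vs Pten, 97 for post PtenRaptor vs WT and 20 for post PtenRaptor vs PtenRictor. In run 1 alone the count was 2181 for pre Pten vs WT, 2075 for pre PtenRictor vs Pten, 127 for post Pten vs WT, 69 for post PtenRictor vs Pten, 1 for post PtenRictor vs WT and 2444 for WT post vs pre. It was 722 for the stage difference of Pten vs WT and 317 for the stage difference of PtenRictor vs Pten. In run 2 alone the count was 25 for pre Pten vs WT, 6 for pre PtenRaptor vs Pten, 164 for pre PtenRaptor vs WT, 21 for post Pten vs WT, 36 for post PtenRaptor vs Pten and 2066 for WT post vs pre. It was 1 for the stage difference of Pten vs WT and 1 for the stage difference of PtenRaptor vs Pten. On runs 1 and 2 only, with a run term for each stage, the count was 484 for pre Pten vs WT, 237 for pre PtenRictor vs Pten, 304 for pre PtenRaptor vs WT, 41 for pre PtenRaptor vs PtenRictor, 101 for post Pten vs WT and 46 for post PtenRaptor vs Pten. It was 129 for post PtenRaptor vs WT, 20 for post PtenRaptor vs PtenRictor, 2857 for WT post vs pre, 4 for the stage difference of Pten vs WT and 1 for the stage difference of PtenRaptor vs Pten. With a run term for each stage the count was 20 for pre PtenRaptor vs Pten, 62 for pre PtenRictor vs Pten, 8 for post PtenRaptor vs Pten, 55 for post PtenRictor vs Pten, 22 for post PtenRaptor vs WT and 139 for WT post vs pre. After a second quantile normalization the count was 3 for pre PtenRaptor vs Pten, 7 for pre PtenRaptor vs PtenRictor, 36 for post Pten vs WT, 6 for post PtenRaptor vs Pten and 16 for post PtenRictor vs Pten. With median centring the count was 3 for pre PtenRaptor vs Pten and 13 for pre PtenRictor vs Pten. With the filter on dim probe sets the count was 26 for pre PtenRaptor vs Pten, 7 for pre PtenRaptor vs PtenRictor, 7 for post PtenRaptor vs Pten and 474 for WT post vs pre. With array weights the count was 16 for pre PtenRaptor vs Pten, 7 for pre PtenRictor vs Pten, 119 for pre PtenRaptor vs WT, 141 for post Pten vs WT, 25 for post PtenRaptor vs Pten and 220 for post PtenRictor vs Pten. It was 130 for post PtenRaptor vs WT, 117 for post PtenRictor vs WT, 61 for post PtenRaptor vs PtenRictor, 1693 for WT post vs pre and 1 for the stage difference of PtenRaptor vs Pten. With the Kdm5d level the count was 27 for post PtenRaptor vs WT and 492 for WT post vs pre. With only the groups compared the count was 0 for pre PtenRaptor vs Pten, 481 for pre PtenRictor vs Pten, 0 for post PtenRaptor vs Pten, 1536 for post PtenRictor vs Pten, 2 for post PtenRaptor vs WT and 5 for post PtenRictor vs WT. It was 3 for post PtenRaptor vs PtenRictor and 2159 for WT post vs pre.

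In run 3 alone, with 16 arrays, limma called 0 genes in each comparison that moved, which were, with the number at an unadjusted p under 0.05, pre Pten vs WT (788), pre PtenRaptor vs Pten (832), pre PtenRictor vs Pten (2403), pre PtenRaptor vs WT (1201), pre PtenRaptor vs PtenRictor (2098), post PtenRaptor vs Pten (1457), post PtenRictor vs Pten (2319) and post PtenRaptor vs PtenRictor (458). With only the groups compared the 0 genes by limma for PtenRaptor against Pten stand beside 996 before and 1792 after selection at an unadjusted p under 0.05, and those of the stage difference in runs 1 and 2 beside 1025. A run with no array of a group, such as run 3 for post_WT, gave no value.

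For the fit of runs 1 and 2 the alternatives moved these counts. Without a run term the count was 135 for pre Pten vs WT, 18 for pre PtenRictor vs Pten, 166 for pre PtenRaptor vs WT, 1 for pre PtenRictor vs WT, 21 for post Pten vs WT and 21 for post PtenRaptor vs Pten. It was 15 for post PtenRictor vs Pten, 360 for post PtenRaptor vs WT and 1 for the stage difference of Pten vs WT. With run as a random block the count was 145 for pre Pten vs WT, 23 for pre PtenRictor vs Pten, 170 for pre PtenRaptor vs WT, 1 for pre PtenRictor vs WT, 21 for post Pten vs WT and 18 for post PtenRaptor vs Pten. It was 13 for post PtenRictor vs Pten, 324 for post PtenRaptor vs WT and 1 for the stage difference of Pten vs WT. With 1 run term for both stages the count was 284 for pre Pten vs WT, 107 for pre PtenRictor vs Pten, 1 for pre PtenRictor vs WT, 30 for post Pten vs WT, 29 for post PtenRaptor vs Pten, 16 for post PtenRictor vs Pten and 1 for the stage difference of Pten vs WT. With median centring the count was 2 for the stage difference of Pten vs WT. With the filter on dim probe sets the count was 385 for pre PtenRictor vs Pten. With array weights the count was 80 for pre Pten vs WT, 41 for pre PtenRaptor vs Pten, 1 for pre PtenRictor vs Pten, 3 for pre PtenRictor vs WT, 164 for post Pten vs WT and 248 for post PtenRaptor vs Pten. It was 68 for post PtenRictor vs Pten, 914 for post PtenRictor vs WT and 1 for the stage difference of Pten vs WT. With the Kdm5d level the count was 3 for pre PtenRaptor vs Pten, 19 for post PtenRaptor vs Pten and 70 for post PtenRaptor vs WT. With only the groups compared the count was 43 for pre Pten vs WT, 4 for pre PtenRaptor vs Pten, 2237 for pre PtenRictor vs Pten, 72 for pre PtenRaptor vs WT, 25 for post Pten vs WT and 4 for post PtenRaptor vs Pten. It was 142 for post PtenRictor vs Pten, 24 for post PtenRaptor vs WT and 0 for the stage difference of Pten vs WT.

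Leaving out 1 array at a time in the planned fit gave, by limma, 10 to 105 for post Pten vs WT, 2 to 53 for post PtenRaptor vs Pten, 7 to 25 for post PtenRaptor vs PtenRictor, 18 to 226 for post PtenRaptor vs WT, 6 to 24 for post PtenRictor vs Pten and 0 to 13 for post PtenRictor vs WT. Further ranges were 31 to 138 for pre Pten vs WT, 2 to 26 for pre PtenRaptor vs Pten, 2 to 8 for pre PtenRaptor vs PtenRictor, 42 to 79 for pre PtenRaptor vs WT, 2 to 36 for pre PtenRictor vs Pten and 0 to 1 for pre PtenRictor vs WT. Further ranges were 0 to 0 for the stage difference of Pten vs WT, 0 to 5 for the stage difference of PtenRaptor vs Pten, 0 to 1 for the stage difference of PtenRictor vs Pten and 1 to 938 for WT post vs pre. For the fit of runs 1 and 2 it gave 28 to 76 for post Pten vs WT, 11 to 55 for post PtenRaptor vs Pten, 51 to 143 for post PtenRaptor vs WT, 6 to 31 for post PtenRictor vs Pten, 0 to 1 for post PtenRictor vs WT and 38 to 1048 for pre Pten vs WT. Further ranges were 7 to 12 for pre PtenRaptor vs Pten, 167 to 503 for pre PtenRaptor vs WT, 0 to 522 for pre PtenRictor vs Pten, 0 to 1 for pre PtenRictor vs WT, 0 to 33 for the stage difference of Pten vs WT and 2320 to 2820 for WT post vs pre.

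The 136 named results called in the planned fit kept their direction in all alternatives, and calls ended 46 times without a run term, 29 times with the random block, 61 times with only the groups compared, 16, 41 and 88 times in runs 1, 2 and 3 alone, 34 times on runs 1 and 2 only, and between 14 and 21 times with a run term for each stage, array weights, median centring, trend and robust settings, the Kdm5d level or a second quantile normalization. Leaving out 1 array ended a call in 543 cases and made one in 2. For runs 1 and 2, 61 calls ended without a run term, 61 with the random block, 58 with only the groups compared, 42 with 1 run term, 34 with array weights, 25 with the Kdm5d level and 222 without 1 array, while median centring, trend and robust settings and a second quantile normalization ended between 4 and 11. There E2f2 and Sytl3, lower in PtenRictor than in Pten cells after selection, turned to 0.26 and 0.13 without a run term and to 0.20 and 0.079 with the random block, none of them called (adjusted p from 0.862 to 0.955). Cyp39a1 in PtenRictor against Pten before selection turned to 0.065 without pre_Pten replicate 1 and was at -1.71 without replicate 2, the lowest.

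Of 105 list calls in the planned fit, 4 held with an estimated correlation, 5 with fry and 87 without a run term. Of 97 calls in runs 1 and 2, 8, 47 and 64 held. Lists that turned sign are given with their adjusted p. For comparisons with both groups the first value is without pre_WT replicate 4 and the second without pre_Pten replicate 1, and the sign turned at the larger of both or, for ribosome biogenesis in Pten vs WT of the planned fit, at the second. They were, in the planned fit, in pre Pten vs WT erythroid markers (0.948 and 0.0525), glycolysis (0.104 and 0.987), ribosome biogenesis (0.0437 and 0.000448), the amino acid response (0.00961 and 0.69) and the cell cycle (0.0010 and 0.854), in pre PtenRaptor vs Pten ribosome biogenesis (0.148) and the cell cycle (0.89), in pre PtenRictor vs Pten ribosome biogenesis (0.058) and the amino acid response (0.93), and in the stage difference of PtenRaptor vs Pten ribosome biogenesis (0.911). For runs 1 and 2 they were, in pre Pten vs WT myeloid markers (0.579 and 3.12e-10), erythroid markers (0.97 and 1.75e-05), ribosome biogenesis (1.71e-19 and 0.593), the amino acid response (0.000146 and 0.593), TCR signal (0.000102 and 0.8996) and pre-selection genes (0.000172 and 0.304), in pre PtenRaptor vs Pten the cell cycle (0.561) and TCR signal (0.784), in pre PtenRictor vs Pten ribosome biogenesis (0.812), the amino acid response (0.938), FOXO1 targets (0.812), TCR signal (0.569) and pre-selection genes (0.251), in WT post vs pre B cell markers (0.636), and in the stage difference of Pten vs WT myeloid markers (0.996 and 3.48e-13), erythroid markers (0.893 and 7.23e-05), glycolysis (0.00799 and 0.992) and the amino acid response (0.00654 and 0.317). Without a run term they were in runs 1 and 2, in pre PtenRictor vs WT ribosome biogenesis (0.995) and the cell cycle (0.702), in post PtenRictor vs Pten the cell cycle (0.00544), and in post PtenRaptor vs WT ribosome biogenesis (0.792) and TCR signal (0.66).

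Without adjustment for run the retained share of PtenRaptor was 93.7% before and 65.1% after selection (SD 41.6 and 251 over splits). On runs 1 and 2 it was 112% and 70.1%. That of PtenRictor was 41.4% and 32.7% without adjustment (SD 61.1 and 437), and -4.44% and 4.73% on runs 1 and 2. With the stricter selection of genes every share stayed within its SD. Leaving out 1 array of the double deletion gave 66.1% to 78.4% and 29.8% to 55.6% in PtenRaptor before and after selection, and 16.2% to 26.02% and -10.3% to 0.689% in PtenRictor, where the highest came without post_PtenRictor replicate 4. The overlap of calls of PtenRictor was 9 before and 7 after selection without a run term. On runs 1 and 2 it was 172 and 24, and 2 and 13 for PtenRaptor. The signal over background sets what these arrays can show, since probe sets near 3.91, the lowest value, hold little range, and the number of arrays limits the precision.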

Other observations

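The values here come from the fit of runs 1 and 2, chosen after the data had been seen, except for the list counts, which belong to the planned fit. Before selection, cells without Pten and Raptor differed from wild type in genes that the rule for named genes chose in that fit. The clock repressor Nr1d1 was higher by 1.08 ± 0.13 (adjusted p = 8.72e-06) and the basement membrane proteoglycan gene Hspg2 by 1.13 ± 0.16 (adjusted p = 0.000127), while the calcium channel gene Cacna1e was at -1.77 ± 0.20 (adjusted p = 6.14e-06). The calls stayed under every alternative and without each array tried in that fit. In Pten cells against wild type, Nr1d1 stood at 0.72 ± 0.12 (adjusted p = 0.000783), Hspg2 at 0.91 ± 0.15 (adjusted p = 0.000757) and Cacna1e at -1.43 ± 0.19 (adjusted p = 6.23e-05). The planned fit gave for PtenRaptor against wild type 0.81 ± 0.20 for Nr1d1 (adjusted p = 0.0667), 0.89 ± 0.25 for Hspg2 (adjusted p = 0.138) and -0.89 ± 0.28 for Cacna1e (adjusted p = 0.242).

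Over the 16 comparisons of the planned fit, camera called the cell cycle list in 13, TCR signal in 11, pre-selection genes in 10, ribosome biogenesis in 9, FOXO1 targets and the interferon response in 8 each, mature single-positive markers in 7, cholesterol synthesis and oxidative phosphorylation in 6 each, and B cell markers in 5. Of all 105 such calls only 4 held with an estimated correlation and 5 with fry. Erythroid and myeloid markers were called in 4 each, the amino acid response, glycolysis and immediate early genes in 3 each, PI3K pathway components and NK markers in 2 each and the innate-like T cell list in 1. Double-negative, γδ T and thymic epithelial markers and fatty acid synthesis were called in 0, with a smallest camera adjusted p of 0.232, 0.179, 0.135 and 0.0698.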
